A study of Arabidopsis thaliana with 24 samples.

How the data were processed

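The series holds 24 one-colour arrays of Arabidopsis thaliana rosette leaf RNA, 4 for each of 6 groups made of 2 genotypes (wild type and the smax1 smxl2 double mutant) and 3 drying times (0, 2 and 4 h). Groups and replicate numbers were taken from the sample titles. At 2 h the free-text description of each sample names the other genotype than its title, source name and genotype field, and the last 3 were used. The series' design text speaks of 3 independent replicates, while 4 arrays per group carry replicate numbers, so whether all 4 come from separate plants is not settled, and p-values then measure the spread between these samples.

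Per the file headers, the arrays are of Agilent design 021169, with probe positions on TAIR10, and were read with Feature Extraction 10.7.3.1. The deposited values are intensities on a linear scale, namely a processed signal for each spot, which per the file headers is background-subtracted and detrended within the array with small substitute values for dim spots, and the raw mean and background signals. The authors' value table holds intensities of 43552 probes that equal the processed signal of the same array within 0.5%, with array medians of 169.3 to 361.2, so no scaling or centring between arrays had been applied to it. How any later normalization was done is not given in the sources used here.

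Each array has 45220 features, of which 1417 control spots were left out. The remaining 43803 spots carry 43603 distinct probes, 50 of them spotted 5 times. Spots marked as outliers by the scanner software, 0 to 40 an array, were left out, spots of 1 probe were averaged, and no spot was saturated. Probes were matched to loci through the transcript accessions in the files and, where none matched, through a locus code in the files, both looked up in the RefSeq gene list of assembly TAIR10.1. Symbols came from that list, from the files where it gave none, or from the gene lists written for the tests. In all 35435 probes matched 1 locus, 475 several and 7693 none, which gave 25854 loci. Only probes of 1 locus were used for genes. Each gene was represented by its probe with the highest mean over all 24 arrays, provided that the probe was well above background on all 4 arrays of at least 1 group. This left 20342 genes, 6338 of them with several probes above the filter, and left out 5 loci whose brightest probe failed it. A weak signal limits what can be said of a gene, and 68.3% to 74.2% of the spots of an array were well above background.

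The values analysed were log2 of the processed signal minus the 75th percentile of the array's non-control spots, a percentile that lay between 1338 and 2479 intensity units. Within groups the median correlation of an array with the others was 0.9866 to 0.9954. Differences were tested with limma 3.58.1 in R 4.3.3 (files read with data.table, version 1.17.8), in 1 fit of 6 group means over the 24 arrays with moderated variances. The comparisons were mutant against wild type at each time, 2 h and 4 h against 0 h within each genotype, and the difference between genotypes of these drying responses. P-values were adjusted within a comparison by the Benjamini-Hochberg method. A gene passed at an adjusted p below 0.05 and a change of at least 2-fold.

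A change against a group in which the probe was not well above background on every array is given as an approximate lower bound. It sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value among probes well above background on that array. That lowest value is taken over all such probes and is not the probe's own detection limit. The bound also makes no allowance for the spread between arrays, so the true change can be smaller. No fold is given where both groups are below background.

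In all 37 lists with 490 members, written before the data were examined, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with a correlation estimated from the data was an alternative. Members past the threshold were counted over all genes tested and adjusted over the list alone. The genes named were fixed by a rule before the data were examined. It took the 2 disrupted genes and, for each genotype comparison, the 8 largest rises and 8 largest falls past the threshold, and 4 of each for the others. These had a symbol and all 4 arrays of one group above the 4 of the other. The rule also took up to 2 rises and 2 falls of each list that moved, and the markers DLK2, KUF1, BBX20, NCED3, RD29A, RD29B, RAB18, PAP1 and DFR. Genes named outside the rule are marked as chosen after their values were seen.

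The alternatives set before the data were examined were normexp background correction (offset 50) of the mean and background signals, quantile normalization, median centring, scaling on 8 spike-in probes, the authors' value table, no filter on dim probes, only probes well above background on all 24 arrays, only the arrays compared, no fold threshold, a variance trend with robust estimation, every probe on its own, the replicate number as a block, and each array left out in turn. Chosen after seeing the data were the mean of the flower markers as a covariate, the testing of probes that match no locus, and slide means as samples. Each group lay on its own slide and each of 3 scan days held both genotypes of 1 time, so genotype comparisons lie within a day and drying time cannot be told apart from the scan day. In all 24 arrays the replicate number was also the place on the slide.

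The steps were tested on simulated data, drawn for every array from the wild-type means at 0 h and each gene's spread within the 6 groups, with changes added to the mutant at 0 h. Of 50 genes changed by each size among 20342, 0 passed the threshold at 1.5-fold, 22 at 2-fold, 45 at 3-fold and 48 at 4-fold, and 1 unchanged gene passed in that comparison. A raised jasmonate list was called upward and 0 of 36 other lists were called. Genes were drawn independently, so how often the list test errs with correlated genes was not tested. Counts of calls were also compared with other splits of the samples, all 35 splits of 8 arrays or 100 draws with a fixed seed.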

Results

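Rosette leaf RNA of Arabidopsis thaliana was profiled on 24 one-colour Agilent arrays, each hybridised with Cy3-labelled cRNA of 1 sample. The plants were 24 days old and were either wild type or smax1 smxl2 double mutants. SMAX1 and SMXL2 are related proteins known as repressors of karrikin signalling, the pathway that responds to smoke-derived karrikins through the receptor KAI2. The aerial parts were cut off and left to dry for 0, 2 or 4 h, which gave 6 groups of 4 arrays. On each array 68.3% to 74.2% of spots were well above background. The arrays differed in brightness, with a 75th percentile of 1338 to 2479 intensity units, and the mutant arrays were the brighter at 0 h (2081 to 2479 against 1530 to 1948) and 2 h (1948 to 2166 against 1700 to 1823), while the ranges overlapped at 4 h. No spot was saturated. All values below are log2 signals relative to the array's own 75th percentile, a change is a difference of group means of 4 arrays against 4, and ± after a change is its standard error. That error rests on a spread of the gene shared by all 6 groups, not on the 8 arrays compared. At 0 h the SD of an array around its group mean was 0.161 to 0.21 in the wild type and 0.247 to 0.326 in the mutant. The error may thus be too small for changes that use the mutant at 0 h. A gene passed the threshold at a limma adjusted p below 0.05 with a change of at least 2-fold, and 20342 genes were tested. Where a probe was not well above background on every array of the dimmer group, the change is given as at least N-fold, with the number of arrays of that group that measured it. This bound is approximate, since its floor is the lowest value among probes well above background, not the probe's own detection limit. A gene that neither group measured on all 4 arrays is named without a size. Each group lay on its own slide, so slide and group cannot be told apart, and p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision, and the median standard error of a change between 2 groups was 0.105.

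The disrupted genes were examined first. The SMAX1 probe, on chromosome 5 at 23387982 to 23388041 (TAIR10, the build named in the array files, as for all coordinates here), was lower in the mutant at every time. Its log2 signal was 1.48 ± 0.042 (SD, n = 4) in the wild type and -1.26 ± 0.13 in the mutant at 0 h. The difference was -2.74 ± 0.10 at 0 h, -4.00 ± 0.10 at 2 h and -3.59 ± 0.10 at 4 h, or 6.68-fold, 16-fold and 12-fold lower, and all 12 mutant arrays lay below all 12 wild-type arrays. The disrupted genes, taken as a list of 2 of which SMAX1 alone passed the threshold, shifted downward at 0 h (camera adjusted p 0.000145, and adjusted p 0.0145 with an estimated correlation). It was the one list call of any comparison that held with an estimated correlation, and it ended when every probe was tested on its own. SMXL2 was read by 4 probes that did not move alike. The brightest, on chromosome 4 at 14850890 to 14850949, differed by -0.69 ± 0.13 at 0 h, 0.35 ± 0.13 at 2 h and 0.41 ± 0.13 at 4 h, all short of 2-fold. The probe at 14850396 to 14850455 differed by -1.03 ± 0.12 at 0 h and by -0.12 and 0.12 at the later times. By contrast, the probes at 14848142 to 14848201 and 14848148 to 14848207 were higher in the mutant at 0 h, by 2.82 ± 0.17 and 3.06 ± 0.14, and were 4.16-fold to 5.12-fold higher at 2 h and 4 h. Where the mutant alleles lie relative to these probes is not given in the sources used here.

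**Figure D1:**
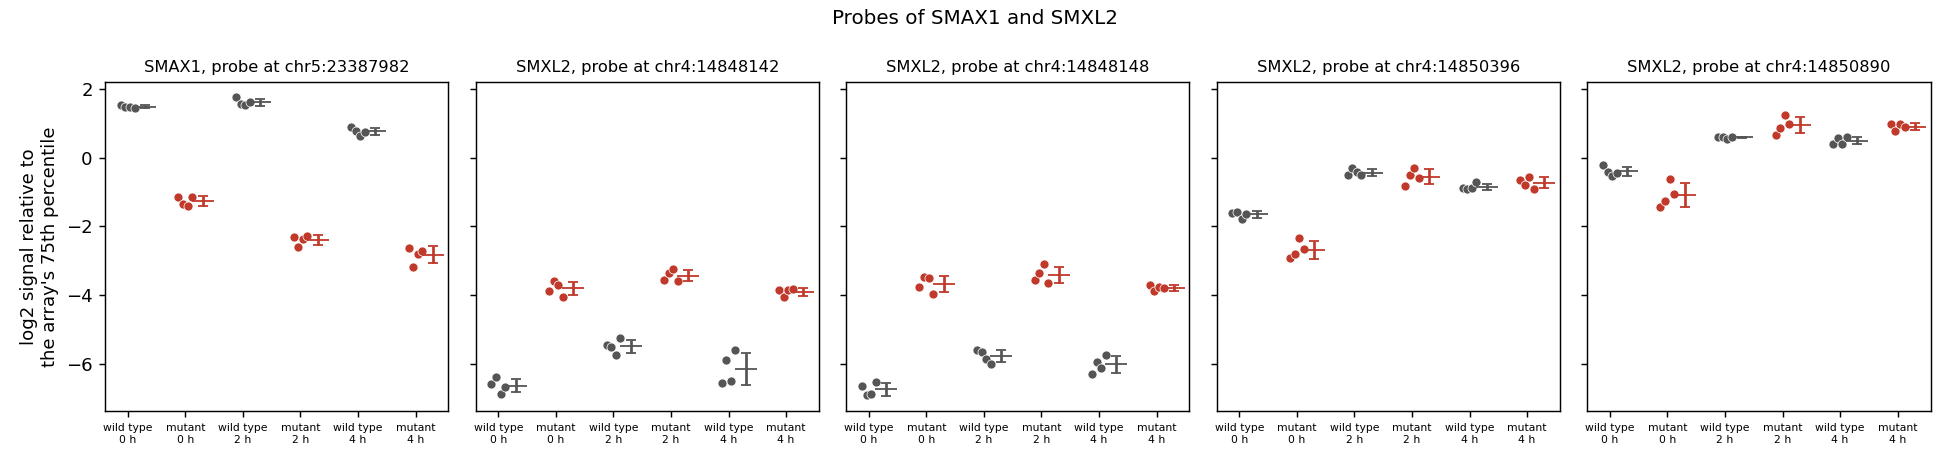
Log2 signal of the SMAX1 probe and of the 4 SMXL2 probes, relative to the array's 75th percentile, in the 6 groups. Each point is 1 array, with the group mean and SD (n = 4) to the right of the points. SMAX1 is lower in all 12 mutant arrays, while the SMXL2 probes at 14848142 and 14848148 are higher in the mutant and those at 14850396 and 14850890 are close to the wild type at 2 h and 4 h.

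The first question was how the mutant differed before water loss. At 0 h, LTP3 and a list of cuticular wax genes were higher in the mutant and a list of flower markers was lower. Both list calls (camera adjusted p 1.62e-13 and 1.39e-05) were lost with an estimated correlation (adjusted p 0.0608 and 0.306). LTP3, a lipid transfer protein gene with its probe on chromosome 5 at 23929485 to 23929544, was 37.7-fold higher (log2 5.24 ± 0.28, adjusted p 2.46e-10). That probe lies within 5 Mb of the SMAX1 probe, so a chromosome segment carried along with the mutant allele stays open for LTP3. The wax ester synthase gene WSD1 was 11.9-fold higher (3.57 ± 0.28) and MAH1, which encodes the midchain alkane hydroxylase of stem wax, rose by 3.04 ± 0.34. The related LTP4 was 2.32 ± 0.39 higher, and whether it lies on a carried segment is open too. RNS1, a ribonuclease gene, was at least 8.77-fold higher (3 wild-type arrays measured it) and EC1.4, of an egg-cell peptide family, at least 3.84-fold (none). DLK2, a homologue of the strigolactone receptor D14 and a marker of karrikin signalling, was 1.94 ± 0.11 higher (adjusted p 8.84e-10). Lowest in the mutant were ORA59, an ERF transcription factor gene of jasmonate and ethylene defence, at least 22.2-fold lower (3 mutant arrays measured it, and at least 11.9-fold without mutant replicate 2), RXF26, at least 13.1-fold (none), MUB5, at least 12.6-fold (3), and AACT1, at -4.58 ± 0.71. The wax and cutin regulator gene SHN1 was at least 6.17-fold lower (1 mutant array measured it) and CRC, which acts in carpels and nectaries, at least 5.11-fold (2 arrays). MAF5, a relative of the floral repressor FLC, differed by -3.42 ± 0.32, and the sugar transporter gene STP11 was at least 2.47-fold lower, with no mutant array measuring it.

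Gene lists fixed in advance moved as follows at 0 h. Of 20 cuticular wax genes 6 were higher and none lower (camera adjusted p 1.62e-13, and adjusted p 0.0608 with an estimated correlation). Of 15 late embryogenesis abundant (LEA) and dehydrin genes, which are made in drying cells, 5 were higher and none lower (adjusted p 0.000138, and 0.579 with an estimated correlation), among them COR15A at 1.92 ± 0.39, LEA7 at 1.91 ± 0.40 and RD29B at least 3.64-fold (3 wild-type arrays measured it). The mean of this list was uneven among the mutant arrays. It was 0.571 in replicate 3, inside the wild-type range of 0.256 to 0.67, and 1.9 in replicate 2. RD29B read -4.59 in mutant replicate 2 and -5.76 to -5.62 in the others. Cutin genes went both ways, 2 higher and 3 lower of 19 (adjusted p 0.982, and adjusted p 0.994 with an estimated correlation). CYP86A2, a fatty acid hydroxylase gene, rose by 1.56 ± 0.10 and the acyl-CoA synthetase gene LACS2 by 1.18 ± 0.11, while the cutin synthase-like gene CUS2 differed by -1.89 ± 0.36. Flower markers were lower, 7 of 8 (adjusted p 1.39e-05, and 0.306 with an estimated correlation), with SEP3 at -2.67 ± 0.37 and AP3 at least 4.59-fold lower (3 mutant arrays measured it, and at least 2.91-fold without mutant replicate 3). Stomatal lineage markers followed, 2 of 6 (adjusted p 0.00142, and 0.579 with an estimated correlation), EPF2 by -1.14 ± 0.24 and TMM by -1.01 ± 0.20. The call of EPF2 ended without mutant replicate 3 (-0.996), and that of TMM without wild-type replicate 3 (-0.923) or mutant replicates 1, 3 or 4 (-0.967, -0.993 and -0.944). TMM also fell short of 2-fold under median centring and spike-in scaling. Smaller shifts were seen for 20 auxin response genes, 1 of them, IAA5, higher by 1.21 ± 0.30 (adjusted p 0.024), and for 21 glucosinolate genes, 3 higher and 4 when adjusted over the list alone (adjusted p 0.024). Expansins (upward, adjusted p 0.025), photosystem and light-harvesting genes (downward, 0.024) and ribosomal protein genes (downward, 0.024) had no member past the threshold. These 5 calls were lost with an estimated correlation, with adjusted p 0.946, 0.946, 0.352, 0.946 and 0.946, and each was also lost under spike-in scaling and without 1 of several arrays, where the adjusted p reached 0.0733 for auxin, 0.141 for glucosinolates, 0.0701 for expansins, 0.231 for photosystem genes and 0.133 for ribosomal genes. For the other lists the counts adjusted over the list alone were equal to those over all genes.

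In total 407 genes passed the threshold at 0 h, 195 higher and 212 lower in the mutant, a split that turned to 243 higher and 139 lower under spike-in scaling. The fixed stress markers NCED3, RD29A, RAB18, DFR and PAP1 stayed within 2-fold, at 0.17 ± 0.13, 0.30 ± 0.33, 0.63 ± 0.19, 0.55 ± 0.46 and -0.01 ± 0.28, and so did the karrikin markers KUF1 and BBX20 at 0.27 ± 0.11 and 0.98 ± 0.34. The mean of the flower markers moved with this comparison, at -2.68 ± 0.21 in the wild type and -4.72 ± 0.84 in the mutant (SD, n = 4), a difference of -2.03 with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allows. With that mean as a covariate, a choice made after the data were seen, 226 genes passed, 173 higher and 53 lower, and LTP4, RNS1, HB32, DMP7, ORA59, RXF26, AACT1, SHN1, CRC, IAA5, CUS2, AP3, SEP3, EPF2 and TMM lost their calls. So did the lists of flower markers, auxin response genes, glucosinolate genes, expansins and ribosomal proteins. Because the covariate is the mean of the flower markers, the loss of that list was fixed in advance. Its members, such as AP3 and SEP3, are pulled the same way. Without mutant replicate 3, whose flower marker mean was the lowest at -5.97, 383 genes passed, 212 higher and 171 lower. With normexp background correction 142 passed, 80 higher and 62 lower, and EC1.4, SHN1, MUB5, STP11, CRC, RD29B, LEA7, EPF2 and TMM lost their calls. HB32 (at least 1.3-fold higher, no wild-type array measuring it) and DMP7, which also passed and was measured on 3 mutant arrays and no wild-type array, had values below 0 there.

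**Figure D2:**
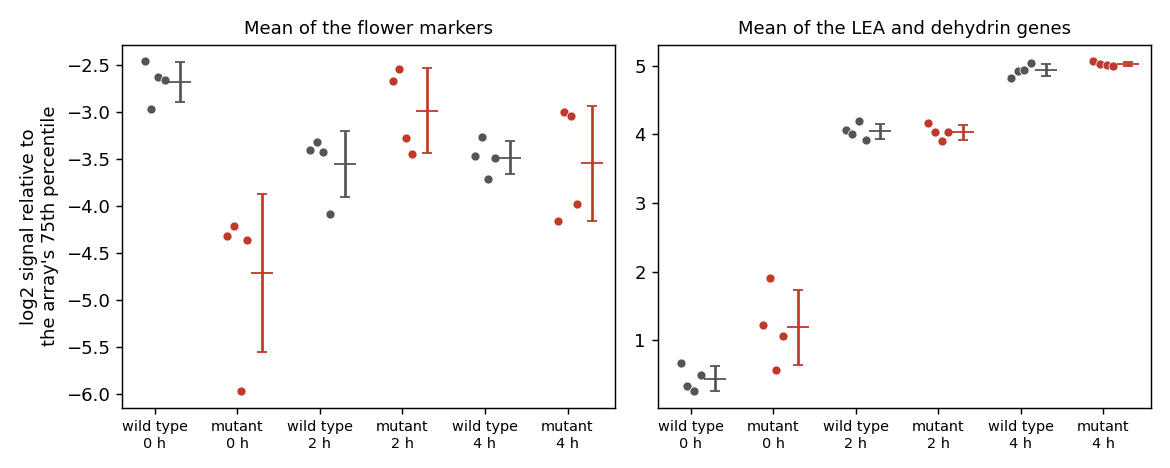
Mean log2 signal of the 8 flower markers (left) and of the 15 LEA and dehydrin genes (right), relative to the array's 75th percentile, in the 6 groups. Points are single arrays and the bars show mean and SD (n = 4). The flower markers are lowest in the watered mutant, at -4.72 on average, and the LEA genes rise with drying time in both genotypes, to 4.94 in the wild type and 5.03 in the mutant at 4 h.

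After 2 h of drying, GA20OX3 and GA3OX1, which encode enzymes of gibberellin synthesis, were among the genes higher in the mutant. GA20OX3 was at least 9.54-fold higher (adjusted p 3.35e-09, no wild-type array measuring it) and GA3OX1 2.05 ± 0.35 higher. LOV1 (locus AT2G02450), a NAC transcription factor gene, rose by 2.41 ± 0.20, and the oxysterol-binding protein gene ORP4B by 1.96 ± 0.19, and the related ORP4A at least 3.25-fold (3 wild-type arrays measured it). The carboxypeptidase-like gene scpl47 passed as higher, measured on 3 mutant arrays and no wild-type array, and the homeobox gene WOX7 was at least 1.02-fold higher, with no wild-type array measuring it. MRD1 was at least 51.9-fold higher on average (2 wild-type arrays measured it), with wild-type replicate 1 at 0.638 close to the mutant and the other wild-type arrays at -6.65 or below, and its call ended without wild-type replicate 4 (fitted log2 5.15). The bound was 185-fold without wild-type replicate 1, 33.2-fold without replicate 2 and 33.6-fold without replicate 3. All 3 karrikin markers passed, DLK2 at 1.63 ± 0.11, KUF1 at 1.28 ± 0.11 and BBX20 at 1.58 ± 0.34. The strigolactone synthesis gene MAX3 was lower, at -1.27 ± 0.45, and lost that call when any 1 of the 8 arrays was left out (-1.43 to -0.882). MAF5 (-3.48 ± 0.32) and the floral repressor FLC (at least 6.69-fold, 2 mutant arrays measuring it) were again lower, as was DR4 (-2.59 ± 0.69). AACT1 was at least 3.81-fold lower (1 mutant array measured it). The dioxygenase gene DOX1, RSL2 and PDE337 passed as lower and were measured on 3, 2 and 3 wild-type arrays and on no mutant array. AACT1, DOX1, RSL2, PDE337 and MAX3 had values above 0 with normexp. Of these, DOX1 lost its call without any 1 of 4 arrays, AACT1 without wild-type or mutant replicate 4 (-1.996 in the first case), and PDE337 without wild-type replicate 1.

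Among the lists at 2 h, the wax genes were again higher, 4 of 20 and none lower (adjusted p 0.000869, and 0.82 with an estimated correlation), with WSD1 at 1.73 ± 0.28 and MAH1 at 1.64 ± 0.34. The cutin list shifted upward (adjusted p 0.000869, and 0.82 with an estimated correlation) with 1 member past the threshold, LACS2 at 1.13 ± 0.11. Flavonoid and anthocyanin enzyme genes shifted upward as a list, with a median of 0.542 over 15 genes (adjusted p 0.00425, and 0.86 with an estimated correlation). Leaf senescence genes shifted downward, with a median of -0.551 over 12 genes (adjusted p 0.00372, and 0.82 with an estimated correlation), and so did salicylate and immunity genes (median -0.551 over 19, adjusted p 0.0274, and 0.86 with an estimated correlation). None of these 3 lists had a single member past the threshold, and the salicylate call ended without wild-type replicates 1 or 4 or mutant replicates 1 or 4 (adjusted p 0.304, 0.0535, 0.0746 and 0.0659), with normexp (0.0639), without a filter on dim probes (0.145) and with the flower marker covariate (0.0605). Of 16 karrikin and strigolactone pathway genes 3 were higher and 1 lower (adjusted p 0.154, and 0.86 with an estimated correlation). Counts adjusted over the list alone were the same as those over all genes, except that the auxin list went from 1 to 0.

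The 2 h comparison gave 370 genes past the threshold, 162 higher and 208 lower. This count depended on the filter on dim probes. It rose strongly without a filter, mainly among the lower genes, and fell with only probes well above background on all arrays. NCED3, RD29A, RD29B, RAB18, DFR and PAP1, all at -0.17 to 0.41, did not differ past it. The flower marker mean was 0.573 higher in the mutant, with an exact two-sided permutation p of 0.143. The split between higher and lower depended on the scaling, with 248 higher and 159 lower under quantile normalization, 195 and 127 under spike-in scaling, and 153 and 43 with normexp, which also ended the calls of WOX7, scpl47, ORP4A, MAF5, FLC and LACS2. Without wild-type replicate 1, 305 genes passed, 162 higher and 143 lower.

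After 4 h, PME2 and XTH19 were among the genes higher in the mutant, and expansins and auxin response genes were higher as lists. Both list calls (camera adjusted p 0.0162 and 0.0015) were lost with an estimated correlation (adjusted p 0.689 and 0.846). The pectin methylesterase gene PME2 was 4.99 ± 0.58 higher (adjusted p 5.75e-06), the xyloglucan endotransglucosylase gene XTH19 rose by 2.77 ± 0.25, the gibberellin-regulated GASA6 by 2.63 ± 0.27, and GER1 by 2.50 ± 0.14. GA20OX3 passed as higher again, measured above background on 3 mutant arrays and no wild-type array. TIP2;3, a vacuolar membrane aquaporin gene, was 2.41 ± 0.24 higher, DMP7 at least 5.11-fold (3 wild-type arrays measured it) and the wax reductase gene CER4 2.304 ± 0.27. Among the genes that were lower, MAF5 was at least 11.6-fold lower (2 mutant arrays measured it) and CKX2, a cytokinin oxidase gene, at least 5.38-fold (none). STP11 was at least 3.69-fold lower (1 mutant array) and MCT1 at least 1.42-fold (none). The senescence protease gene SAG12 differed by -2.17 ± 0.40, the trypsin inhibitor gene KTI1 by -2.10 ± 0.47 and DR4 by -2.09 ± 0.69, the last of which lost its call when any 1 of 6 arrays was left out (-2.15 to -1.73). DLK2 stood at 1.68 ± 0.11 and BBX20 at 2.03 ± 0.34 higher. KUF1, at 0.91 ± 0.11, fell short of 2-fold, and MAX3 was lower, at -1.72 ± 0.45.

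Of the lists at 4 h, auxin response genes were higher, 6 of 20 and none lower (adjusted p 0.0015, and 0.846 with an estimated correlation), such as SAUR24 at 1.304 ± 0.34 and SAUR21 at 1.23 ± 0.33. Expansins rose too, 3 of 7 (adjusted p 0.0162, and 0.689 with an estimated correlation), with EXPA3 at 1.90 ± 0.24 and EXPA1 at 1.80 ± 0.17. Wax genes were higher in 3 of 20 (adjusted p 0.0015, and 0.846 with an estimated correlation), including MAH1 at 1.80 ± 0.34. Cutin genes were higher in 3 of 19 (adjusted p 0.00816, and 0.846 with an estimated correlation), including CYP86A2 at 1.36 ± 0.10 and the acyltransferase gene GPAT4 at 1.23 ± 0.08. The clade A protein phosphatases, which repress abscisic acid (ABA) signalling, shifted downward (adjusted p 0.0286, and 0.846 with an estimated correlation) with 1 of 9 past the threshold, AHG1 at -1.02 ± 0.33. That call of AHG1 ended without any 1 of 4 arrays (-1.01 to -0.935), and the list's ended without wild-type replicate 3 (adjusted p 0.0529), with normexp (0.101) and with only probes well above background on all arrays (0.0872). Photosystem and light-harvesting genes had no member past the threshold (adjusted p 0.0334, and 0.892 with an estimated correlation) and lost their call under each other scaling of the arrays. The karrikin and strigolactone list held 2 higher and 1 lower (adjusted p 0.195, and 0.892 with an estimated correlation). Counts adjusted over the list alone did not differ from these.

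At 4 h 496 genes passed, 294 higher and 202 lower. NCED3, RD29A, RD29B, RAB18, DFR and PAP1 lay between -0.59 and 0.17 with no call. The flower marker mean differed by -0.06 (exact two-sided permutation p 0.857). Under spike-in scaling the split turned to 228 higher and 306 lower, and with normexp 167 genes passed, 117 and 50. GA20OX3, XTH19, DMP7, CKX2, MCT1, STP11, SAG12, DR4, BBX20, SAUR24, SAUR21, AHG1 and MAX3 lost their calls there.

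The 3 times use separate arrays and so can be compared. Of the genes higher in the mutant at 0 h, 46 were also called higher at 2 h, against 1.55 expected of independent lists, and 55 at 4 h, against 2.82. Among the lower genes the shared counts were 32 (2.17 expected) and 26 (2.11 expected). In all, 53 genes passed the threshold in 1 direction at all 3 times, 35 higher and 18 lower. Among the 35 were WSD1, MAH1, CER4, LACS2 and the ketoacyl reductase gene KCR2 (1.45, 1.66 and 1.37 at 0, 2 and 4 h). The transporter gene ABCG22, which affects stomatal water loss, was higher by 1.13, 1.82 and 1.99, and DLK2 by 1.94, 1.63 and 1.68. Among the 18 were MAF4 at -2.70, -1.97 and -1.58, MAF5 at -3.42 and -3.48 at 0 and 2 h and at least 11.6-fold lower at 4 h, and FLC at -2.03 at 0 h and at least 6.69-fold lower at 2 h. FLC was measured on 2 mutant arrays at 2 h and 2 at 4 h, and MAF5 on 2 at 4 h. The germination gene DOG1 (-1.04, -1.001 and -1.13) and the pathogenesis-related gene PR4 (-1.85, -1.62 and -1.18) were lower too. KCR2, ABCG22, MAF4, DOG1 and PR4 were singled out after their values were seen. Under spike-in scaling 40 higher and 11 lower genes passed at all 3 times. With normexp 18 of these 53 still passed at all 3 times, and with the flower marker covariate 34 genes did. With only probes well above background on all arrays 35 genes did. With each slide's mean as 1 sample and the scan day as a block, a fit of 6 values chosen after the data were seen, the genotype difference averaged over the times passed for 4 genes (3985 at an unadjusted p under 0.05), against 249 over the arrays, and SMAX1 stood at -3.44 with an adjusted p of 0.0647.

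Far more genes passed the threshold between times than between genotypes. No group was cut and kept from drying for 2 or 4 h. Responses to cutting or to elapsed time therefore cannot be told apart from drying, here or in the comparisons of responses. Between times, drying cannot be told apart from the scan day either, since each time had its own. In the wild type 6629 genes passed at 2 h, 3214 higher and 3415 lower than at 0 h, and 7317 at 4 h, 3441 higher and 3876 lower, a split that turned to 4681 higher and 2588 lower under spike-in scaling. Among the highest rises were those of ELI3-2, a cinnamyl alcohol dehydrogenase-like gene, at least 5000-fold at 2 h and at least 5130-fold at 4 h, UGT76E12, a glycosyltransferase gene, at least 2420-fold and 1950-fold, and the ERF gene RAP2.6, at least 2930-fold and 2620-fold. The terpene synthase gene TPS04 rose at least 2610-fold at 2 h, and LEA7, measured on all arrays, 4110-fold at 4 h. At 0 h RAP2.6 and TPS04 were measured on 1 array, and ELI3-2 and UGT76E12 on none. The expansin gene EXPA8 fell by 6.52 ± 0.45 at 2 h and at least 723-fold at 4 h, AGP3, an arabinogalactan protein gene, at least 37-fold and 62.1-fold, BZIP61 at least 41.8-fold at 2 h and the wall enzyme gene XTH25 at least 435-fold at 4 h. AACT1 was at -6.55 ± 0.71 at 2 h and at least 213-fold lower at 4 h. AGP3 was measured on no dried array and BZIP61 on none at 2 h, and EXPA8, XTH25 and AACT1 were measured on 2, 1 and 3 arrays at 4 h.

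Drought and ABA genes fixed in advance were examined next in the wild type. NCED3, the ABA synthesis gene induced by water loss, rose by 3.65 ± 0.13 at 2 h and 3.68 ± 0.13 at 4 h, RD29A by 4.28 ± 0.33 and 4.31 ± 0.33, RAB18 by 3.20 ± 0.19 and 4.73 ± 0.19, and RD29B at least 29.6-fold and 169-fold (3 arrays measured it at 0 h). At 2 h, 14 of 15 LEA and dehydrin genes rose (adjusted p 2.96e-07, and 0.175 with an estimated correlation), with LEA7 at 9.80 ± 0.40, and 15 of 15 rose at 4 h. Of 9 clade A phosphatases 8 and then 9 rose (2 h adjusted p 1.27e-05, and 0.175 with an estimated correlation), HAI1 by 8.27 ± 0.35 at 2 h and AHG1 at least 120-fold at 4 h (no 0 h array). ABA synthesis genes rose in 7 of 9 at both times (2 h adjusted p 0.00354, and 0.175 with an estimated correlation), and 3 of 4 ABA catabolism genes, CYP707A1 by 2.23 ± 0.21 at 2 h (adjusted p 0.0353, and 0.175 with an estimated correlation). Of 10 ABA receptor genes 3 rose and 4 fell at 2 h, PYL7 by 2.74 ± 0.17 up and PYL4 by -1.94 ± 0.27 (adjusted p 0.726, and 0.854 with an estimated correlation). CBF and DREB factors rose in 9 of 11 (2 h adjusted p 0.000195, and 0.177 with an estimated correlation), with DREB19 at 6.12 ± 0.25 at 4 h, while CBF1 and CBF2 were then lower, at -1.04 ± 0.37 and -1.31 ± 0.28. Both of these calls ended under spike-in scaling and with normexp, and that of CBF1 also without wild-type replicates 1 or 4 of 0 h (-0.737 and -0.968) or of 4 h (-0.95 and -0.903). Of 10 dehydration transcription and related genes 8 rose at 2 h, NAC019 by 5.72 ± 0.27 and RD20 by 5.68 ± 0.21 (adjusted p 3.62e-05, and 0.177 with an estimated correlation). Proline and raffinose metabolism genes gave 6 rises and 2 falls of 11 at 2 h (adjusted p 0.00699, and 0.175 with an estimated correlation), with RS5 up by 5.38 ± 0.17 and PRODH1, of proline breakdown, at -1.85 ± 0.42.

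Jasmonate genes rose almost as a whole after cutting and drying, whose parts in this cannot be told apart. Of 27 members 26 rose at 2 h and 24 at 4 h (adjusted p 1.34e-13 and 5.34e-10, and 0.114 and 0.219 with an estimated correlation), AOC3 by 8.47 ± 0.43 and LOX3 by 7.73 ± 0.18 at 2 h. Flavonoid and anthocyanin enzyme genes rose in 12 and then 14 of 15 (2 h adjusted p 1.63e-05, and 0.177 with an estimated correlation), DFR by 5.31 ± 0.46 at 2 h and 6.69 ± 0.46 at 4 h. Among their regulators 7 of 12 rose and 1 fell at 2 h (adjusted p 0.0245, and 0.175 with an estimated correlation), PAP1 by 7.75 ± 0.28 and the repressor gene MYBL2 by -1.20 ± 0.23, a call that ended without wild-type replicate 1 of 2 h (-0.986). Glutathione transferases rose in 21 of 27 (2 h adjusted p 1.15e-05, and 0.177 with an estimated correlation), GSTU3 at least 798-fold (no 0 h array), while GSTU27 and GSTF3 were lower, at -2.43 ± 0.14 and -1.81 ± 0.38. Glucosinolate genes rose in 13 of 21 (0.000195, and 0.401 with an estimated correlation), MYB29 by 4.35 ± 0.20 and MYB28 going the other way at -2.66 ± 0.24. Wax genes rose in 13 of 20 at both times and fell in 2 (2 h adjusted p 0.000618, and 0.3 with an estimated correlation), with the elongase gene KCS2 at 5.66 ± 0.17 and the wax repressor gene DEWAX at -3.93 ± 0.19. Heat shock genes rose in 9 of 11 at 2 h (0.000173, and 0.177 with an estimated correlation), HSFA2 by 6.04 ± 0.27. Senescence genes rose in 7 of 12 at 2 h and 10 at 4 h (adjusted p 0.00352 and 0.00159, and 0.201 and 0.232 with an estimated correlation), SAG12 at least 26.3-fold at 4 h (no 0 h array), while SEN1 was lower at both times, at -3.22 ± 0.21 and -4.11 ± 0.21, and WRKY53 at 4 h, at -1.11 ± 0.24. The call of WRKY53 ended under each other scaling of the arrays, with normexp and without wild-type replicate 1 of 0 h (-0.97) or replicate 4 of 4 h (-0.981). The scavenging enzymes of reactive oxygen rose in 3 of 20 at 2 h (0.0353, and 0.175 with an estimated correlation), with DHAR1 at 2.13 ± 0.07. With normexp the calls of the 2 h lists of ABA catabolism, flavonoid regulators and scavenging enzymes ended. The last also ended under quantile normalization, spike-in scaling, either other filter on dim probes and the flower marker covariate (adjusted p 0.0532 to 0.116 with normexp included), that of proline and raffinose genes (0.28) with every probe tested on its own, and that of the flavonoid regulators with every probe or only probes well above background on all arrays.

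Photosystem and light-harvesting genes fell in the wild type, 3 of 33 at 2 h and 12 at 4 h (adjusted p 0.00236 and 9.47e-06, and 0.65 and 0.464 with an estimated correlation), RBCS1B by -1.19 ± 0.25 and then -3.31 ± 0.25, and the 2 h call ended with quantile normalization. Auxin response genes held 5 rises and 10 falls of 20 at 2 h (adjusted p 0.47, and 0.854 with an estimated correlation), and 1 rise and 13 falls at 4 h (0.00159, and 0.464 with an estimated correlation), with SAUR20 at -5.89 ± 0.37 and IAA29 at -6.09 ± 0.31. Of 7 expansins 4 fell and 1 rose at 4 h (0.262, and 0.482 with an estimated correlation), EXPA11 by -5.42 ± 0.23 and EXPA10 by 4.53 ± 0.20. Guard cell markers fell in 4 of 11 at 2 h (0.292, and 0.65 with an estimated correlation), MYB60, which acts in stomatal opening, by -2.36 ± 0.16. Clock genes went both ways at 2 h, 4 up and 7 down of 17 (0.47, and 0.854 with an estimated correlation), CCA1 by 3.58 ± 0.15 and ELF4 by -3.40 ± 0.16. Whether the 3 times were collected at the same hour of the day is not given in the sources used here. In the karrikin and strigolactone list, MAX3 rose at least 10.8-fold at 2 h and 49.2-fold at 4 h (no 0 h array measured it), DLK2 by 1.56 ± 0.11 and 1.22 ± 0.11, and BBX20 was lower by -4.30 ± 0.34 and -4.33 ± 0.34, while KUF1 was lower at 2 h by -1.51 ± 0.11 (list adjusted p 0.826 and 0.845, and 0.921 and 0.972 with an estimated correlation).

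The same comparisons were made in the mutant. It gave 5935 genes at 2 h, 3034 higher and 2901 lower (3386 and 1475 with normexp), and 6884 at 4 h, 3398 higher and 3486 lower. Across genes, which are not independent replicates, the changes of both genotypes correlated at r 0.955 at 2 h and 0.961 at 4 h. Both genotypes of a time shared a scan day, so differences between days enter both changes. They may raise this correlation and the number of shared calls. Of the wild-type calls at 2 h, 2714 higher and 2543 lower genes were called in the same direction in the mutant, and 1 and 10 in the opposite direction. Among the most extreme at 2 h were BSMT1, a methyltransferase gene of salicylate, at least 749-fold higher, UGT76E12, at least 1280-fold, TPS04, at least 1460-fold, and CYP94B3, of jasmonate breakdown, by 10.24 ± 0.42. At 4 h they included UGT76E12, at least 836-fold, NATA1 by 10.86 ± 0.69, CSLG2 by 10.74 ± 0.40 and the heat shock factor gene HSFA6B, at least 694-fold. Among the largest falls were those of EXPA8 (-8.41 ± 0.45 at 2 h, at least 700-fold at 4 h), XTH25 (-7.10 ± 0.55, then at least 257-fold), the cyclin gene CYCP4;1 (-6.33 ± 0.15 at 2 h), BZIP61 (at least 76-fold at 2 h), and at 4 h XTH33 (at least 99.6-fold) and SAUR15 (at least 96.9-fold). Of the rising genes, BSMT1 was measured on no mutant array at 0 h, UGT76E12 on 1, and TPS04 and HSFA6B on 2. Of the falling ones, BZIP61 was measured on 1 array at 2 h, and EXPA8, XTH25, XTH33 and SAUR15 on 1, 1, 0 and 3 at 4 h. NCED3 rose by 3.55 ± 0.13 at 2 h and 3.44 ± 0.13 at 4 h, RD29A by 3.81 ± 0.33 and 4.03 ± 0.33, RD29B by 3.298 ± 0.27 and 5.53 ± 0.27, RAB18 by 2.69 ± 0.19 and 4.27 ± 0.19, DFR by 5.16 ± 0.46 and 5.56 ± 0.46, and PAP1 by 7.74 ± 0.28 and 7.15 ± 0.28. Without mutant replicate 3 of 0 h the rises were 10.9 for CYP94B3 at 2 h, 11.9 for NATA1 at 4 h (10.2 without replicate 4) and 5.87 and 6.26 for DFR at 2 h and 4 h. DLK2 rose by 1.24 ± 0.11 and stood at 0.96 ± 0.11 at 4 h, short of 2-fold, and BBX20 was lower by -3.70 ± 0.34 and -3.28 ± 0.34.

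By list, the mutant at 2 h had 26 of 27 jasmonate genes higher (adjusted p 3.78e-14, and 0.0981 with an estimated correlation), 14 of 15 LEA genes (2.13e-06, and adjusted p 0.2 with an estimated correlation) and all 15 flavonoid enzyme genes (1.01e-06, and adjusted p 0.161 with an estimated correlation). Also higher were 8 of 9 clade A phosphatases (2.79e-05, and adjusted p 0.159 with an estimated correlation), 9 of 11 CBF and DREB factors (0.00026, and adjusted p 0.2 with an estimated correlation) and 7 of 9 ABA synthesis genes (0.00303, and adjusted p 0.159 with an estimated correlation). At 4 h 25 jasmonate genes, 15 LEA genes, 15 flavonoid enzyme genes and 9 phosphatases were higher (adjusted p 4.6e-10, 1.61e-06, 4.71e-06 and 5.82e-05, and 0.287 each with an estimated correlation). Of 33 photosystem genes 8 were lower at 4 h (adjusted p 0.00385, and 0.742 with an estimated correlation), RBCS1B at -4.055 ± 0.25. Flower markers, of which 3 of 8 fell in the wild type at both times, were higher in 6 of 8 at 2 h (adjusted p 0.0795, and 0.602 with an estimated correlation) and 5 at 4 h (0.324, and 0.848 with an estimated correlation), SEP2 at least 7.06-fold and 3.98-fold (3 arrays measured it at 0 h), or 4.59-fold and 2.59-fold without mutant replicate 3 of 0 h. The salicylate list, with 6 higher and 5 lower of 19 at each time (2 h adjusted p 0.903, and 0.972 with an estimated correlation), was the one list whose count changed when adjusted over the list alone, from 11 to 10.

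**Figure D3:**
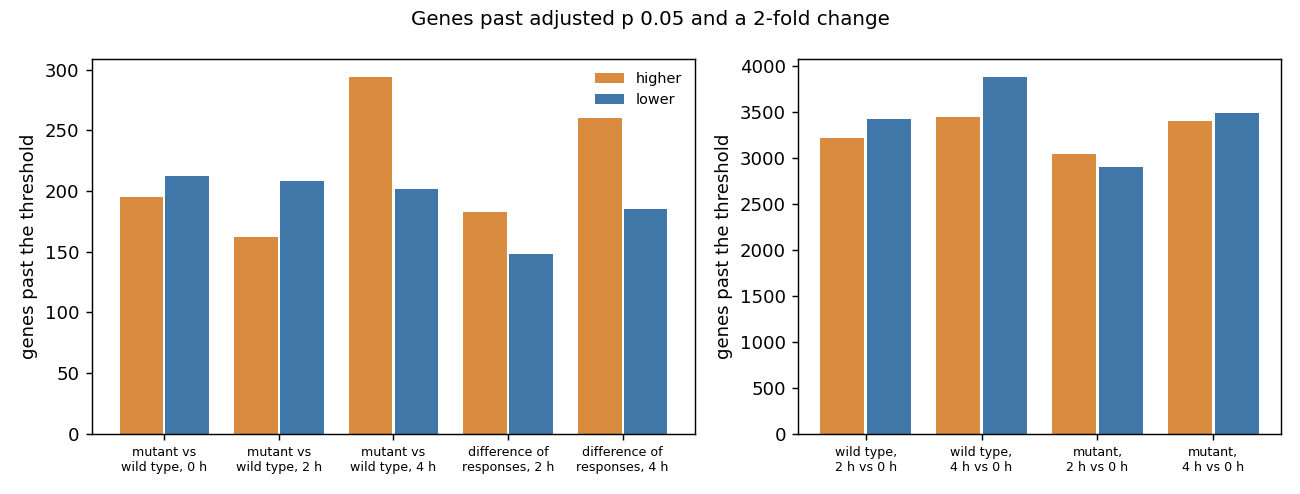
Number of genes past the threshold (adjusted p below 0.05 and a change of at least 2-fold) in each comparison, as bars from 0, split into higher and lower in the first-named group. Left, genotype at each time and the difference between the responses of the genotypes, with 331 and 445 genes in the last 2 comparisons. Right, drying within each genotype, with 5935 to 7317 genes.

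The last question was which genes responded to drying differently in the mutant. The difference of the responses (mutant minus wild type) passed the threshold for 331 genes at 2 h, 183 positive and 148 negative, and for 445 at 4 h, 260 and 185. Of these, 11 and 7 genes were called in opposite directions in the genotypes. LTP3 was at -4.01 ± 0.40 and -4.69 ± 0.40 (adjusted p 3.05e-05 and 1.39e-06), with all arrays measuring it. LEA7 rose less in the mutant, at -2.17 ± 0.56 and -2.39 ± 0.56, and like LTP3 it started from a higher signal there at 0 h. RNS1 had fitted differences of -3.80 ± 0.57 and -3.21 ± 0.57 and RD29B of -1.59 ± 0.38 and -1.87 ± 0.38, both measured on 3 wild-type arrays at 0 h and both higher in the mutant then. The 2 h calls of LEA7 and RD29B ended under spike-in scaling, and RD29B was at 0.1808 at 2 h with normexp. NCED3, RD29A, RAB18, DFR, PAP1, DLK2 and BBX20 did not pass at either time. PME2 was at 4.76 ± 0.82 at 4 h, and AP3, measured on 3 mutant arrays at 0 h, had a fitted difference of 3.56 ± 0.99 at 2 h. Other calls rested on a 0 h group with 2 or more arrays below background, so that no size is given here. On the positive side these were RXF26, SHN1 and CRC at both times, measured on 0, 1 and 2 mutant arrays at 0 h. On the negative side they were ELI3-2 at both times, measured on no wild-type array at 0 h, SBT3.3 at 2 h, measured on no wild-type and 1 mutant array at 0 h, and CKX2 at 4 h, which was measured on wild-type arrays of 4 h alone. ELI3-2 lost the call without any 1 of 13 arrays at 2 h or 12 at 4 h, and SBT3.3 was at 0.3074 with normexp and lost its call with the flower marker covariate. KUF1 passed at 2 h (1.01 ± 0.16) and not at 4 h (0.65 ± 0.16). The main SMXL2 probe was positive at both times (1.04 ± 0.18 and 1.095 ± 0.18), against -0.77 and -0.58 at the probe starting at 14848142. SMAX1 was at -1.26 ± 0.14 at 2 h and -0.85 ± 0.14 at 4 h. Near the 2-fold line, KUF1 lost its call under each other scaling and without any 1 of 4 arrays (0.912 to 0.97), and SMXL2 without any 1 of 4 at 2 h (0.925 to 0.98) and without mutant replicate 1 of 0 h at 4 h (0.982). SMXL2 also lost its call with normexp (0.9396), median centring (0.9815) and every probe tested on its own (0.9146) at 2 h, and under spike-in scaling (0.8601) at 4 h, and SMAX1 lost its 2 h call with normexp (-0.7508). AP3 lost its 2 h call without any 1 of 5 arrays (3.41 to 3.57), and stood at 2.39 without mutant replicate 3 of 0 h.

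Among the lists, flower markers were positive in 7 of 8 at 2 h and 4 at 4 h (8 and 7 adjusted over the list alone; camera adjusted p 3.77e-06 and 0.000937, and 0.502 and 0.946 with an estimated correlation). Stomatal lineage markers were positive in 4 of 6 at 2 h (6 adjusted over the list alone; 0.000158, and 0.502 with an estimated correlation), EPF2 at 1.55 ± 0.34. Cutin genes were positive in 6 of 19 and then 3 (8 and 4 adjusted over the list alone; 0.00425 and 0.00289, and 0.607 and 0.965 with an estimated correlation), CUS2 at 2.32 ± 0.51 and 1.85 ± 0.51. LEA and dehydrin genes were negative in 3 of 15 at both times (4 and 3 adjusted over the list alone; 0.000158 and 0.0078, and 0.502 and 0.965 with an estimated correlation). Their mean was 0.437 in the wild type and 1.19 in the mutant at 0 h. It was 4.04 and 4.03 at 2 h and 4.94 and 5.03 at 4 h, so the genotypes differed mainly before drying. Wax genes were negative in 2 of 20 and positive in 1 at 2 h and negative in 2 at 4 h (4 and 3 adjusted over the list alone; 0.000177 and 0.000937, and 0.502 and 0.946 with an estimated correlation), WSD1 by -1.85 ± 0.40 and -2.00 ± 0.40 and KCS2 by -1.53 ± 0.23 and -1.71 ± 0.23. Glutathione transferases shifted downward at both times, with 1 and then 3 of 27 past the threshold (2 and 3 adjusted over the list alone; 0.000158 and 0.00851, and 0.502 and 0.965 with an estimated correlation), GSTU17 by -1.48 ± 0.26 and -1.22 ± 0.26, and GSTU9 was positive at 4 h, at 1.28 ± 0.24. Glucosinolate genes were negative in 2 of 21 each time (0.011 and 0.00851, and 0.831 and 0.965 with an estimated correlation), namely MYB76 and MYB29, the latter at -1.54 ± 0.28 and -1.50 ± 0.28. MYB76 was measured on 2 wild-type arrays at 0 h and was at 0.2187 at 2 h with normexp. Of the cytokinin response genes 2 of 14 were negative and 1 positive at 4 h (0.436, and 0.965 with an estimated correlation), ARR16 at -1.67 ± 0.25. The clade A phosphatase list shifted downward at both times, with 0 and 1 of 9 past the threshold (0 and 2 adjusted over the list alone; 0.011 and 0.00289, and 0.607 and 0.946 with an estimated correlation). Lists that shifted with no member past the threshold were flavonoid enzymes (0.00155), ribosomal proteins (0.00172) and photosystem genes (0.00383) upward and salicylate genes (0.0319) downward at 2 h, and photosystem genes upward at 4 h (0.000224). With an estimated correlation their adjusted p values were 0.607, 0.734, 0.831, 0.831 and 0.965. The arrays of the 0 h mutant carried several of these calls. Without its replicate 2 the LEA list at 4 h and the phosphatase list at 2 h were at adjusted p 0.07 and 0.138, without replicate 1 the glucosinolate list was at 0.0893 and 0.0702, and without replicate 3 the glutathione transferases at 4 h were at 0.0575. The glucosinolate call at 4 h also ended without wild-type replicate 1 (0.0715) or mutant replicate 2 (0.0884) of 4 h, and the salicylate call without any 1 of 7 arrays (0.0575 to 0.324). With the flower marker covariate the calls of the flower marker, cutin, glucosinolate and glutathione transferase lists ended at both times and that of the salicylate genes at 2 h (adjusted p 0.292 to 0.806). For the flower marker list this was fixed in advance, the covariate being its own mean. With normexp the 2 h calls of cutin (0.0691), photosystem (0.273), ribosomal (0.852) and salicylate genes (0.0558) and the 4 h call of glutathione transferases (0.102) ended. Under spike-in scaling those of glutathione transferases (0.245) and glucosinolate genes (0.151) at 4 h ended, under quantile normalization those of photosystem genes at both times (0.978 and 0.578), with median centring that of salicylate genes (0.117), and without a filter on dim probes those of glucosinolate (0.0691) and salicylate genes (0.105) at 2 h. The phosphatase past the threshold at 4 h was AHG1, measured on no array at 0 h, whose call ended without any 1 of 13 arrays.

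The flower marker mean again moved with this comparison. It was -4.72, -2.98 and -3.54 at 0, 2 and 4 h in the mutant and -2.68, -3.56 and -3.49 in the wild type. With it as a covariate 37 genes passed at 2 h, 13 positive and 24 negative, and 235 at 4 h, 110 and 125. RXF26, SHN1, CRC, RNS1, CUS2, MYB29, MYB76 and ELI3-2 then lost their calls at both times, AP3, KUF1, RD29B, LEA7, EPF2, WSD1, GSTU17 and SBT3.3 at 2 h and AHG1 at 4 h. AP3 is itself among the markers averaged in the covariate. Without mutant replicate 3 of 0 h the counts were 328 (160 positive, 168 negative) and 395 (217, 178), and without wild-type replicate 1 of 2 h the count at 2 h was 288. Normexp gave 122 and 80 genes, spike-in scaling 180 and 526, the latter 140 positive and 386 negative, and quantile normalization split the 4 h calls into 196 and 243. Among the calls that ended with normexp were SHN1, CRC, RD29B, WSD1, MYB76, LEA7 and ELI3-2 at both times, EPF2 and SBT3.3 at 2 h, and RXF26, RNS1, CUS2, CKX2 and AHG1 at 4 h. Those of AP3, EPF2 and ELI3-2 at 2 h ended under spike-in scaling.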

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

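Of the tests here, those of slides, crossed labels, a linked segment, a constant genotype effect on flower tissue, a difference already present at 0 h and the flower marker covariate were chosen after the result was seen.

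Other splits of the samples were counted for each comparison. For mutant against wild type, 1 of the 35 splits, the real one, gave as many genes at 0 h (407, highest other 33), 1 of 35 at 2 h (370, highest other 10) and 1 of 35 at 4 h (496, highest other 95). For drying, 1 of 35 did so in each case, with 6629 (highest other 3) and 7317 (highest other 1) in the wild type and 5935 (highest other 29) and 6884 (highest other 92) in the mutant. For the difference of responses, 2 of 100 draws gave as many at 2 h (331) and 1 of 100 at 4 h (445, highest other 104). The highest draw at 2 h, 982 genes, kept the genotype of all 8 arrays at 0 h and exchanged it for all 8 at 2 h, which adds the genotype differences of both times and is a structure of the samples, and the second highest gave 265. Chance in how the arrays fall into groups is thereby made unlikely for the comparisons of 2 groups, 1 of 35 being the smallest share the splits allow. Every other split mixes the 2 groups, so any difference between them, of slides too, widens the spread and lowers the count. The draws for the difference of responses also break the genotype difference common to the times. They therefore cannot decide whether the responses alone differ by chance. An effect of the slides is not excluded, since each group lay on 1 slide. Nor is it settled that the arrays come from separate plants.

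The first pattern is the set of 53 genes changed in 1 direction at all 3 times, where independent lists would share 0.044. That number takes every gene as equally likely to be called, which was not checked. Slides of different times are separate, so slide effects that are independent of each other would share few genes. Differences that recur between the genotypes, such as the brighter mutant arrays at 0 h and 2 h, are not excluded by this. Crossed genotypes at 2 h are excluded by SMAX1, at -3.998 in the arrays titled mutant. Position stays open, because 18 of 52 genes (34.6%, SMAX1 left out) lay within 5 Mb of SMAX1 or SMXL2, against 3784 of 20341 (18.6%) of all tested genes (one-sided Fisher exact p 0.00451). Part of the set may therefore come from chromosome segments carried along with the mutant alleles, MAF5 at 26001072 on chromosome 5 being 1 such gene, while the other 34 genes lie elsewhere. MAF4, which carries the locus number just before that of MAF5, is open in the same way. CER4, DMP7 and ORP4B lie on chromosome 4, as SMXL2 does. Their distances from it are not given here, so a carried segment stays open for them too. LTP3, which is not in the set, also lies within 5 Mb of SMAX1. An effect of the lost proteins is open for both parts and was not tested apart.

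The second pattern is the low flower markers of the mutant at 0 h, with a mean difference of -2.03 (SEP3, for example, read -3.16 against -0.49). A constant genotype effect on flower tissue does not by itself account for this, since the difference was 0.573 at 2 h and -0.06 at 4 h. With each group on its own slide, such an effect overlaid by differences between samplings is not excluded. Less flower tissue in these 4 samples is consistent with a second list of flower genes, whose values were looked at after it was written, with a median of -0.584 over the 9 of 20 that were tested, against 0.0882 at 2 h. That shift is smaller than that of the markers, and no single one of the 9 passed at 0 h (from -0.9119 to 0.1103, limma adjusted p 0.0678 or above). The list's 1 call came at 4 h, where its median was -0.0797. SHP1 was lower in the mutant there, at -1.539 (limma adjusted p 1.11e-05), against -0.8107 at 2 h and -0.1548 at 0 h. A genotype effect on flower genes that drying removes stays open and was not tested.

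The third pattern is the 331 and 445 genes with different drying responses. Of them 61.9% at 2 h and 42.9% at 4 h had their larger genotype difference at 0 h, and at 4 h, where the share lies between the values that would have decided, a difference already present before drying cannot be told apart from one that arises during it. With the flower marker mean as a covariate 37 genes passed at 2 h, 26 of them among the 331, and 235 at 4 h, 149 of them among the 445. Among the 331 the median change in the direction of the call went from 1.53 to 1.22 and its median standard error from 0.348 to 0.515, and among the 445 from 1.5 to 1.45 and from 0.363 to 0.475, so that calls ended through lost precision as well as smaller changes, and flower tissue cannot be told apart from lost precision at either time. A genotype effect on the response stays open.

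Single arrays far from the 3 others of their group were found in 36 of 444 sets of 4 values, where chance marks about 1 in 20. Among list means these were, with the range of the others where it helps, auxin response in mutant replicate 2 at 2 h (0.343, others 0.618 to 0.652), cutin in mutant replicate 3 at 0 h (-1.48), the karrikin and strigolactone list in mutant replicate 1 at 0 h (-0.849), flower markers in mutant replicate 3 at 0 h (-5.97) and wild-type replicate 4 at 2 h (-4.08), photosystem genes in wild-type replicate 4 at 0 h (6.96), ribosomal proteins in wild-type replicate 3 at 4 h (3.69), and salicylate genes at 4 h in wild-type replicate 4 (-2.27) and mutant replicate 2 (-0.475). In the wild type at 0 h the genes were RNS1 in replicate 2 (-7.62), LTP4 in replicate 3 (-3.84) and NCED3 in replicate 1 (-1.26). In the wild type at 2 h they were HB32 (-7.28), STP11 (-7.19), RD29B (-1.52) and PME2 (-3.19), all in replicate 3, and MRD1 in replicate 1 (0.638). In the wild type at 4 h they were EC1.4 in replicate 3 (-5.1), BBX20 in replicate 2 (-5.8), PDE337 in replicate 1 (-6.28) and SBT3.3 in replicate 4 (-5.11). In the mutant at 0 h they were ORA59 (-9.81), RD29B (-4.59), PME2 (-2.36) and CER4 (-0.942) in replicate 2, PDE337 (-6.3) and MCT1 (-8.34) in replicate 1, CKX2 in replicate 4 (-10.1) and AP3 in replicate 3 (-9.69). In the mutant at 2 h they were RNS1 in replicate 1 (4.31), RXF26 (-8.55) and SHN1 (-6.84) in replicate 4 and RD29B in replicate 3 (-2.74). In the mutant at 4 h they were LOV1 (-1.86) and CKX2 (-7.92) in replicate 2 and ORP4A in replicate 1 (-5.34). No array of the group measured HB32, STP11, MCT1 or CKX2 well above background, so their values have no order and no array stands apart by them. RNS1 in the wild type, ORA59, AP3 and RXF26 were below background on the named array alone, PDE337 in the mutant was above it on that array alone, and MRD1 on 2 arrays.

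By the test of the difference itself, drying responses of named genes differed between the genotypes at 2 h for RXF26 (6.09), SHN1 (5.05), CRC (3.9), AP3 (3.56), LTP3 (-4.01), RNS1 (-3.8), ELI3-2 (-3.75), SBT3.3 (-2.91), SMAX1 (-1.26), SMXL2 (1.04), KUF1 (1.01) and RD29B (-1.59). At 4 h they differed for RXF26 (5.44), PME2 (4.76), SHN1 (4.54), CRC (3.67), LTP3 (-4.69), ELI3-2 (-3.65), CKX2 (-3.46), RNS1 (-3.21), SMXL2 (1.1) and RD29B (-1.87). These are fitted values, and their size cannot be read for RXF26, SHN1, CRC, ELI3-2, SBT3.3 and CKX2, which were below background on 2 or more arrays of a 0 h group. AP3, RNS1 and RD29B were below it on 1, and AP3 stood at 2.39 without mutant replicate 3 of 0 h.

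Signals outside the values used for the comparisons were found for 2 further SMXL2 probes and for probes that match no locus. The SMXL2 probe at 14848142 was higher in the mutant by 2.82, 2.06 and 2.24 at 0, 2 and 4 h, and that at 14848148 by 3.06, 2.36 and 2.22. Of the probes matched to no locus 108, 133 and 172 passed the threshold between genotypes at 0, 2 and 4 h.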

How the results depend on the processing

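Of the alternatives, the flower marker covariate, the testing of unmatched probes and the slide means were chosen after the data were seen. The 222 named genes gave 580 results over the comparisons, of which 537 passed and 412 kept their call in every setting, and of 105 list calls 64 kept theirs in every setting but the estimated correlation, with which 1 did. Where a value below moved or turned, the cause was not tested, except that a stricter filter tests fewer genes and dropping the fold threshold admits smaller changes. Dim signals limit the results, since every gene that turned, except CUS2, was not well above background on all arrays. A fit with the slide as a random block was not run because each group lay on its own slide, and the genotype comparisons already lie within a scan day.

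Counts are given in the order mutant against wild type at 0, 2 and 4 h, wild-type drying at 2 and 4 h, mutant drying at 2 and 4 h, and the difference of responses at 2 and 4 h. With normexp the genotype counts were 142 (80 higher, 62 lower), 196 (153, 43) and 167 (117, 50), the response differences 122 and 80, the genes shared at all 3 times 18, and mutant drying at 2 h split as 3386 and 1475. With only probes well above background on all arrays the genotype counts were 221, 180 and 262, the response differences 201 and 257 and the shared genes 35. Without a filter the 2 h genotype count was 968 (175 higher, 793 lower). With no fold threshold the 9 counts were 4382, 4771, 5121, 15826, 16456, 15185, 16097, 1784 and 2540, and 804 genes were shared. With the flower covariate the counts were 226 at 0 h, 37 and 235 for the response differences and 34 shared, and with unmatched probes 89 were shared. Spike-in scaling gave 180 and 526 (140, 386) response differences, and splits of 243 and 139 at 0 h, 195 and 127 at 2 h, 228 and 306 at 4 h, and 4681 and 2588 for wild-type drying at 4 h. Quantile normalization split 248 and 159 at 2 h and 196 and 243 for the 4 h response difference. Slide means gave 4 genes against 249 for the genotype difference averaged over the times.

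The median of all genes shifted by over 0.1 under spike-in scaling for the genotypes at 0 h (0.109) and 4 h (-0.126), wild-type and mutant drying at 4 h (0.342 and 0.108) and the 4 h response difference (-0.235). It did so with normexp at 2 h for the genotypes (0.15), mutant drying (0.224) and the response difference (0.151), and with median centring for wild-type drying (0.107 and 0.187) and mutant drying at 4 h (0.121).

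SMXL2 passed with no fold threshold at 0 h (-0.6864) and 4 h (0.4085), with the flower covariate at 0 h (-1.157), and by its strongest probe when every probe was tested (3.059, 2.356 and 2.224). Of the lists called, 10 at 0 h became 6 with median centring, 5 with spike-in scaling and 1 with an estimated correlation. The 5 at 2 h became 14 with normexp, 10 with spike-in scaling, 8 with quantile normalization, with every probe and with the flower covariate, and 0 with an estimated correlation. For the 7 other comparisons an estimated correlation left 0.

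With normexp these named genes turned: HB32 (-0.09364), DMP7 (-0.05752) and MYB76 (-0.0637) at 0 h, DOX1 (0.04646), AACT1 (0.1558), RSL2 (0.5803), PDE337 (0.375) and MAX3 (0.1581) at 2 h, PYL6 in mutant drying at 2 h (0.2076), and SBT3.3 (0.3074), RD29B (0.1808) and MYB76 (0.2187) in the 2 h response difference. With the flower covariate CRC (0.1031) and AP3 (0.9698) turned at 0 h, AP3 in mutant drying at 4 h (-0.3469), CRC (-0.01031), AP3 (-1.16), CUS2 (-0.08454) and SEP2 (-0.8993) in the 2 h response difference and SEP2 in that at 4 h (-0.6876). AP3 and SEP2 are among the markers averaged in that covariate, so their turning says little.

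Leaving out each array in turn gave 361 to 433, 301 to 431, 432 to 632, 6325 to 6804, 7174 to 7478, 5866 to 5977, 6855 to 6921, 239 to 398 and 354 to 502 genes, and 47 to 56 shared. The lists called ranged from 6 (without mutant replicate 1) to 11 at 0 h and from 4 to 8 (without wild-type replicate 2) at 2 h.

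Same-numbered arrays of different groups deviated together only slightly more than others. Their 60 pairs had a median r of 0.027 (-0.30 to 0.31, 19 above 0.1). The 180 pairs of different numbers had a median of -0.014 (-0.47 to 0.38, 37 above 0.1). Of 24 arrays 9 were closest to their own number. The numbers were therefore not taken to pair the samples, though a weak pairing is not excluded. With the replicate number as a block the counts were 403, 371, 497, 6633, 7317, 5936, 6886, 339 and 450, with 53 shared, and of the named genes only ELI3-2 in the 2 h response difference lost its call.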

Other observations

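MRD1 differed among the wild-type arrays themselves. Its probe, on chromosome 1 at 19963495 to 19963554, read 0.179 to 0.992 on the 12 mutant arrays. Of the 12 wild-type arrays 4 were near that level, namely replicate 4 at 0 h (1.01), replicate 1 at 2 h (0.638) and replicates 1 and 4 at 4 h (0.349 and 0.151). The other 8 were lower, from -6.85 up to -3.17 in replicate 2 at 0 h. No explanation was tested.

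AT5G57720, which carries the next locus number after SMAX1 and was singled out after its values were seen, was higher in the mutant at 0 h by 2.505 on the log2 scale (SE 0.324, limma adjusted p 3.28e-05), with all arrays of both groups well above background. At 2 h and 4 h no wild-type array measured it well above background. Lower bounds were computed only for genes named by the rule, so no fold is given. Among the lists not described so far, aquaporins gave 8 rises and 4 falls of 17 in the wild type at 2 h (adjusted p 0.0882, and 0.623 with an estimated correlation). Markers of meristem and dividing cells were lower in 3 of 4 in the wild type at 4 h (adjusted p 0.123, and 0.464 with an estimated correlation). Vascular markers had 1 of 5 higher in the wild type at 2 h (adjusted p 0.47, and 0.854 with an estimated correlation).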
